A study of Saccharomyces cerevisiae with 36 samples.

How the data were processed

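The values are the log2 ratios of the 2 channels deposited by the authors in the series matrix, 1 per spot and array. The steps from scanned image to ratio, including background treatment and any scaling, are not given in the sources used here. Base 2 was checked on 117 recurring values: 45 lay within 3e-08 of the logarithm of a ratio of whole numbers up to 400 at base 2, against 3 at each other base tried. Array medians ranged from −0.29 to 0.54 over spots with a gene symbol, and no scaling was added. Each array held 3456 spots, or 864 probes with 4 spots each. Spots with exactly 0 (8 to 985 per array) were treated as missing, as were blanks (0 to 1110). Usable spots of a probe were averaged. The SD between spots of a probe had medians of 0.09 to 0.22 per array.

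The annotation deposited with the array gave 1 gene symbol to 2896 spots (724 probes), none to 560 and several to 0, with 230 symbols, of which all 230 were found in the gene table. Probe roles are not stated and were inferred as likely from order: a gene with 3 neighbouring probes was read as junction, intron and exon, and a gene with 5 as junction and intron for each of 2 introns, then exon. This covered 216 and 7 genes. The basis is that intron probes rose and junction probes fell in strains with impaired splicing, and that lariat introns are seen in dbr1. The same changes are reported below as results, so they are not independent evidence for the roles. The 5 genes HIS4, ADH1, GAL10, GAL1 and FAS1 without introns were added to the exon values. For HMRA1, MTR2 and part of ACT1 and RPS16A the role was uncertain (21 probes), and these were kept out of both indices.

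The ratio was turned to mutant over wild type by the channel that the labels give to the mutant, with channel 2 over channel 1 as the likely direction. All 36 arrays entered 1 limma fit (lmFit and eBayes, limma 3.58.1 in R 4.3.3) with a coefficient per mutant and a common dye term, for the intron index, the junction index, the exon values and all probes. The fit left a median of 17 residual degrees of freedom, with prior degrees of freedom of 9.14 for introns, 4.72 for junctions and 9.27 for exon probes. P-values were adjusted by Benjamini and Hochberg within a mutant and measure, at 0.05. Differences between mutants were contrasts in the same fit, and every mutant was also set against hsp104. Paired strains in a contrast were chosen because they share a complex or step.

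Gene lists were tested with camera at a preset correlation of 0.01 and with an estimated correlation, adjusted over lists and mutants within a measure, where at least 3 members were measured. The estimated correlation was computed once per list and measure over all arrays and used for every mutant. Adjustment can give many tests the same adjusted p. Members were counted over all genes and adjusted over the list alone. The 11 lists were ribosomal protein genes (97 on the array), snoRNA host introns (8 genes), meiotic genes (8), Mer1-dependent introns (2), mRNA processing and export genes (9), cytoskeleton genes (12), secretion genes (12), ubiquitin and proteasome genes (8), mitochondrial genes (6), glycolytic genes (ADH1 alone) and stress genes (0 on the array). Ribosomal protein introns were also compared with all others by 100000 permutations across introns. The length and splice site classes that were planned were not analysed here, since no genome was used here.

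Genes were named by a rule: the 4 highest and 2 lowest intron indices past the threshold, the 3 lowest and 1 highest junction indices and the 2 highest and 2 lowest exon changes, doubled for prp4-1a, dbr1, prp17, prp18 and upf3. The rule added up to 4 called members per list, the deleted genes, the 5 genes called in most mutants, and ACT1, RPL28, RPL30, REC107, YRA1, DBP2 and TUB3. Where the text names fewer than the rule allows, those first in rank were taken. RPS9A and NOG2 among list members of prp4-1a, the junctions of YML6 in the comparison of msl1 with cus2 and of RUB1 in that of prp18 with prp4-1a, the introns of RPL29, SAR1, HNT1 and SPO1 in comparisons of mutants, and the genes drawn in the figures were chosen after their values were seen.

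The design, the lists, the rule for named genes and these alternatives were fixed before the data were examined: centring on all probes or on exon and intronless probes, no dye term, probes on all arrays only, a trend and robust spread, deletion strains only, a threshold of 0.01, spots joined by their median, the 2 arrays of a mutant alone, hsp104 as reference, and each array left out. Zeros kept as values, at least 2 usable spots per probe, and array weights by mutant were chosen after seeing the data. The procedure was tested on simulated data before use: of changes of size 1, from 94.7% to 100% were recovered, and of size 0.5 from 44.4% to 100%. The share of false calls was 1.75% to 7.69%, above the nominal 5% in 4 of 6 settings. A contrast of prp17 and prp18 recovered 38 of 50 changes of size 1 with 2 of 148 called in error. A list test with no shift passed in 3 of 100 simulations and with a shift of 0.5 in 100 of 100. The simulated items varied independently, each with the same spread on all arrays. These figures therefore do not cover correlated genes, such as ribosomal protein introns (estimated correlation 0.651), or strains whose arrays lay further apart. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, version 1.17.8 of data.table was used in R, and figures were drawn with matplotlib 3.10.9.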

Results

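Splicing was surveyed in 18 budding yeast mutants on 36 2-colour arrays, with 2 arrays per mutant on which the channels of mutant and wild-type RNA were exchanged. The mutants were 17 deletion strains and prp4-1a, a temperature-sensitive allele of a protein gene of the U4/U6 snRNP. The series title presents the deleted genes as factors of mRNA processing that cells can live without. Per the labels, deletion strains were grown at 26 °C, and prp4-1a and its own wild type were moved from 26 to 37 °C for 2 h. The labels of dbr1 instead describe pooled RNA of haploid and diploid cells, some dividing and some sporulating, so its growth differed from that of the other strains. Each array carried 3456 spots, of which 2896 had a gene symbol, and 2127 to 2792 of these gave a usable ratio per array (median 2478).

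The probes covered 230 introns of 223 genes. By the roles inferred from probe order, each had a probe in the intron, at the exon junction and in an exon. Values are log2 ratios of mutant over wild type. The intron index is the intron probe minus the exon probe of the same gene and follows unspliced RNA or excised intron relative to all RNA of the gene. The junction index is the junction probe minus the exon probe and follows spliced RNA relative to all RNA of the gene. Introns and junctions are said to rise or fall by their index. An index also rises where the exon probe falls more than the other probe. Unless stated otherwise, n = 2 arrays per mutant, errors are standard errors from limma with 1 spread shared by all arrays, and a change is an adjusted p under 0.05 within the mutant. For strains whose arrays lay further apart than most, these errors and p-values are too small. These are prp4-1a and mud13, dbr1 for introns and, to a lesser degree, snu17 for junctions and prp18 for exon probes. For strains whose arrays lay closer than most they are too large. At introns the spread was 0.555 times the median in hsp104, 0.574 in mud1, 0.618 in snu40 and 0.681 in mud2. Low counts there do not show that effects are absent. Whether the 2 arrays of a mutant came from separate cultures is not given in the sources used here, so p-values measure only the spread between arrays, which may be technical. The number of arrays limits the precision, and without intensities it is unknown which probes lay above background.

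Probes of a deleted gene check the labels and the direction of the ratio, and MUD1 and STO1 were the deleted genes with named probes. In mud1, which lacks a protein of the U1 snRNP, the MUD1 exon probe averaged −2.56 ± 0.10 (SD, n = 2) and the junction probe −3.91 ± 0.04. In gcr3, which lacks the large subunit of the nuclear cap-binding complex (gene STO1), the STO1 exon probe averaged −5.59 ± 0.31 and the junction probe −5.46 ± 0.63. On the other arrays the exon probes stayed between −0.73 and 0.36 for MUD1 and between −1.25 and 0.87 for STO1. The MUD1 intron probe was lower too (−1.81 ± 0.03), whereas the STO1 intron probe was higher in gcr3 (1.06 ± 0.13). Channel 2 over channel 1 is therefore the likely direction of the deposited ratio, on the ground of these deleted genes. Exchanged arrays had opposite signs in affected strains (r from −0.94 in prp4-1a, dbr1 and snu66), which shows the exchange of channels but not the direction. The direction is not settled by the labels. With the mutant in channel 2, the hsp104 array correlated at −0.36 with snu17 and at −0.43 with prp4-1a, and prp4-1a at −0.40 with cus2 and −0.36 with nam8. In the other orientation the same pairs correlated at 0.31, 0.29, 0.55 and 0.40, and with the mean of each probe over the arrays removed at −0.0908, −0.09, −0.215 and −0.172. Read with the sign turned, the introns raised in prp4-1a (208), snu17 (196) and nam8 (10) would be lowered, the 1 lowered intron of prp4-1a and of nam8 would be raised, and every other direction given here would turn likewise. The STO1 exon probe would then be 48.1-fold and the MUD1 exon probe 5.9-fold higher in the strains that lack these genes. Those values argue against the turned sign, although the STO1 intron probe went the other way.

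In prp4-1a after 2 h at 37 °C, nearly every intron was raised. Of 214 introns, 208 rose and 1 fell, with a median index of 3.38. RPL29 led (5.20 ± 0.22, or 36.7-fold), followed by RPL43B (5.16 ± 0.20) and RPS16A (5.12 ± 0.25), all of which encode ribosomal proteins. ACT1, the actin gene, rose by 4.49 ± 0.23 and COF1, the gene of the actin-severing protein cofilin, by 4.44 ± 0.17. The lowered index was that of NOG2, a GTPase gene of ribosome assembly (−0.66 ± 0.18). Its exon probe rose by 1.34 ± 0.14, so this does not show a fall of the intron RNA itself. The NOG2 intron could be tested in 2 of 18 mutants. At junctions 116 fell and 34 rose by the index. At the junction probes themselves 179 of 215 fell and 8 rose as deposited, with a median of −1.765. A junction index also rises where the exon probe falls further, so the 34 need not mean more spliced RNA. RUB1, which encodes a ubiquitin-like modifier, fell by 3.14 ± 0.10, and ARF2 and CNB1 each stood at −2.79 (± 0.19 and ± 0.15). The junction of RPS16A went the other way (4.38 ± 0.12). It could be tested in 3 of 18 mutants, and part of the RPS16A probes were of uncertain role. Since roles were inferred from probe order, a wrong role for this probe is possible. Exon probes had a median of −1.24, with RPL29 at −3.96 ± 0.18 and RPS25B at −3.16 ± 0.13, while NOG2 (1.34 ± 0.14) and GLC7, the gene of a protein phosphatase (0.90 ± 0.16), rose. In total 18 transcripts rose and 170 fell as deposited. After each array was centred on its exon and intronless probes, here called exon centring, the median moved by 1.1 and the split was 98 to 110. After centring on all probes the shift was 0.37 and the split 45 to 138.

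By gene group in prp4-1a, introns rose in 98 of 99 ribosomal protein introns (also 98 when adjusted over the list alone), in all 9 measured of mRNA processing and export genes, all 13 of cytoskeleton genes, all 12 of secretion genes, all 8 of ubiquitin and proteasome genes and all 6 of mitochondrial genes, with the same counts adjusted over the list alone. SAR1, the GTPase of COPII vesicle formation, rose by 3.64 ± 0.19, LSM2 by 4.00 ± 0.20 and COX4, a subunit of cytochrome oxidase, by 3.90 ± 0.18. The ribosomal protein introns had a median of 4.03 against 2.48 elsewhere (camera adjusted p = 0.000506, and adjusted p = 0.938 with an estimated correlation). Introns of the snoRNA host genes stood lower, at 1.99 against 3.45, with 8 of 9 raised and the NOG2 index lowered (adjusted p = 0.0181, and adjusted p = 0.938 with an estimated correlation). At exon probes 95 of 97 ribosomal protein genes fell and RPS9A rose (0.69 ± 0.13), with a median of −2.32 that was −1.25 with exon centring (adjusted p = 3e-20, and adjusted p = 0.166 with an estimated correlation). Meiotic genes stood above the rest (median 0.22, adjusted p = 0.00226), with adjusted p = 0.0493 with an estimated correlation and adjusted p = 0.124 with ribosomal protein genes left out of the comparison set. Among them SPO1 (0.31 ± 0.12) and REC107 (0.29 ± 0.13) rose and HFM1 fell (−0.34 ± 0.14; 0.73 with exon centring), although none of the 6 passed when adjusted over the list alone. ADH1, the glycolytic gene on the array, rose by 0.43 ± 0.10. The 2 prp4-1a arrays lay further apart than those of other mutants, with 3.72 times the median residual spread for introns and 4.55 times for junctions. The errors given for prp4-1a come from the shared spread and understate this. With arrays weighted by the spread of their mutant, the lowered junctions numbered 47.

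**Figure D1:**
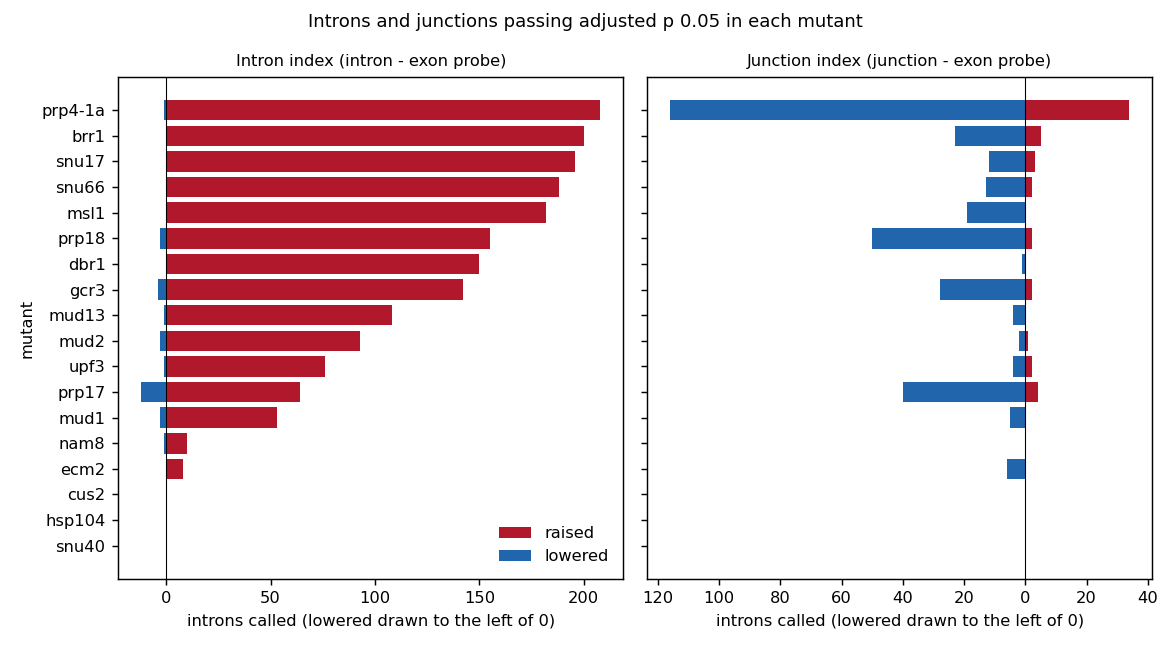
Number of introns whose intron index (left) or junction index (right) passed an adjusted p of 0.05 in each of 18 mutants (2 arrays each), with raised introns drawn to the right of 0 and lowered to the left. Raised introns range from 208 in prp4-1a to 0 in cus2, hsp104 and snu40, and lowered junctions are most frequent in prp4-1a (116), prp18 (50) and prp17 (40). With arrays weighted by the spread of their mutant, lowered junctions were most frequent in mud1 instead.

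The deletions brr1, msl1, snu17 and snu66, which touch snRNP assembly, the U2 snRNP or the tri-snRNP, raised most introns by a moderate amount. In brr1, which lacks a factor of snRNP biogenesis, 200 of 212 introns rose and 0 fell (limma; 0 also at an unadjusted p under 0.05), with a median index of 1.25. RIM1, which encodes a mitochondrial DNA-binding protein, rose by 2.67 ± 0.19, RUB1 by 2.51 ± 0.17 and the downstream intron of EFM5 (intron 2), a methyltransferase gene, by 2.43 ± 0.17. At junctions 23 fell and 5 rose, and the lowest were RPS22B intron 1 (−1.10 ± 0.14) and SRB2, a Mediator subunit gene (−1.02 ± 0.24). Exon probes had a median of −0.20, with RPS22B at −1.64 ± 0.14, SEC27, a COPI coat gene, at −1.47 ± 0.24 and SMD2, an snRNP core protein gene, at 0.46 ± 0.08. All 12 secretion, all 11 cytoskeleton, all 8 ubiquitin and proteasome and 92 of 98 ribosomal protein introns rose, with the same counts adjusted over the list alone. All 6 mitochondrial genes fell at exon probes, COX5B by 1.29 ± 0.14 (camera adjusted p = 0.0123, and adjusted p = 0.417 with an estimated correlation). Exon probes split 4 up to 92 down as deposited and 46 to 53 with exon centring (shift 0.21). Against hsp104 in place of the wild type 4 junctions were lower, 4 to 5 with an array left out and 62 with arrays weighted by spread.

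In msl1, which lacks the U2 snRNP protein U2B'', 182 of 193 introns rose and 0 fell (limma; 0 also at an unadjusted p under 0.05), with a median of 1.21. EFM5 intron 2 rose by 2.77 ± 0.17, SNC1, a gene of vesicle fusion, by 2.27 ± 0.19, RUB1 by 2.25 ± 0.17 and UBC13, a ubiquitin-conjugating enzyme gene, by 2.22 ± 0.19. Junctions fell at 19 introns (1 to 7 with an array left out, 5 against hsp104 and 44 with arrays weighted by spread), led by RPS22B intron 1 (−0.89 ± 0.14), and RPS22B (−1.40 ± 0.14) and UBC9, the SUMO-conjugating enzyme gene (−1.08 ± 0.10), were lowest at exon probes, against a median of −0.26. All 9 secretion introns rose, with a median of 1.87 against 1.20 elsewhere (camera adjusted p = 0.0269, and adjusted p = 0.938 with an estimated correlation), as did 90 of 94 ribosomal protein introns (median 1.15, lower than the 1.31 of others; adjusted p = 0.0181, and adjusted p = 0.938 with an estimated correlation). The counts adjusted over the list alone were the same. Exon probes split 2 to 91, and 14 to 21 with exon centring (shift 0.26). Cus2, another U2 factor, gave a different picture: in cus2, limma called 0 of 196 introns, 0 junctions and 0 exon probes, against 5, 2 and 8 at an unadjusted p under 0.05. With arrays weighted by spread 2 introns were called. In a direct comparison 158 of 177 introns were higher in msl1 than in cus2, for example SAR1 (2.10 against −0.03), along with 6 lower junctions such as YML6 (−0.58 against 0.10) and 43 lower exon probes such as COX4 (−0.81 against 0.31).

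In snu17, which lacks a protein of the U2-associated RES complex, 196 of 208 introns rose and 0 fell (limma; 0 also at an unadjusted p under 0.05), with a median of 1.35. TAN1, a tRNA modification gene, rose by 2.70 ± 0.14 and LSM2 by 2.56 ± 0.20, followed by RUB1 and RIM1 (2.38 each, ± 0.17 and ± 0.19). At junctions 12 fell and 3 rose. RPS22B intron 1 (−1.04 ± 0.14) and STO1 (−0.67 ± 0.10) fell and TAN1 rose (1.00 ± 0.27). At exon probes CIN2, a tubulin folding gene, stood at −1.18 ± 0.11 and TAN1 at −1.09 ± 0.09, against a median of −0.24. In all, 94 of 98 ribosomal protein, all 11 secretion and all 8 ubiquitin and proteasome introns rose, also when adjusted over the list alone. The exon split was 5 to 77, and 19 to 24 with exon centring (shift 0.26). Against hsp104 2 junctions were lower.

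In snu66, which lacks a tri-snRNP protein, 188 of 203 introns rose and 0 fell (limma; 0 also at an unadjusted p under 0.05), with a median of 1.25. YIP3 rose by 3.02 ± 0.16, VMA10, a subunit gene of the vacuolar proton pump, by 2.84 ± 0.21, NYV1, a vacuolar SNARE gene, by 2.80 ± 0.19 and LSM2 by 2.79 ± 0.20. Junctions fell at 13 introns (2 to 4 with an array left out and 39 with arrays weighted by spread), with YNL050C lowest (−1.09 ± 0.10), and rose at 2. At exon probes SRC1 (1.10 ± 0.10) and YNL050C (0.77 ± 0.08) rose and COX5B fell (−0.78 ± 0.14), in a split of 6 to 28 that was 20 to 34 with exon centring and 4 to 56 with centring on all probes (shift −0.12). Of 98 ribosomal protein introns 89 rose (the same adjusted over the list alone), with a median of 1.13 against 1.32 (camera adjusted p = 0.00192, and adjusted p = 0.938 with an estimated correlation). Compared directly with prp4-1a, 175 of 199 introns were lower in snu66 and 2 higher. RPL29 stood at 0.89 in snu66 against 5.20 in prp4-1a, while HNT1 was higher (0.78 against −0.26). Junctions differed at 101 introns, 76 of them higher in snu66, and exon probes at 177. Strain, wild type and temperature differ between this pair as well as the mutation.

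The U1 snRNP mutants and mud2 showed smaller changes. In mud1, 53 introns rose and 3 fell, with a median index of 0.19. EFM5 intron 2 rose by 1.70 ± 0.17, SNC1 by 1.52 ± 0.19, RUB1 by 1.48 ± 0.17 and NYV1 by 1.34 ± 0.19, whereas RPL42B (−0.69 ± 0.26) and RPL20B (−0.54 ± 0.18) fell. Of 98 ribosomal protein introns 1 rose and 3 fell, and limma called 0 of them when adjusted over the list alone, where over all introns 72 rose and 7 fell at an unadjusted p under 0.05. Their median was −0.03 against 0.47 for other introns (camera adjusted p = 3.25e-19, and adjusted p = 0.938 with an estimated correlation). The exon probes of ribosomal protein genes, which the index subtracts, had a median of 0.217, against 0.0116 over all exon values. Secretion introns rose at 6 of 12 (9 adjusted over the list alone; adjusted p = 0.0254, and adjusted p = 0.938 with an estimated correlation) and ubiquitin and proteasome introns at 4 of 7 (4; adjusted p = 0.0181, and adjusted p = 0.938 with an estimated correlation). At junctions 5 fell, with NHP6B at −0.80 ± 0.14. They include MUD1 (−1.35 ± 0.19), the deleted gene, whose probes read residual signal and say nothing of splicing. With an array left out 12 to 15 introns and 1 to 2 junctions passed. Exon probes split 0 to 18, with COX5B at −0.81 ± 0.14, and 42 to 32 with exon centring (shift −0.0012). Against hsp104 19 introns were higher, and with arrays weighted by spread 106 rose. With that weighting mud1 had more lowered junctions than any other strain.

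In nam8, which lacks another U1 snRNP protein, 10 of 220 introns rose and 1 fell. SAR1 rose by 1.69 ± 0.19, EFM5 intron 2 by 1.39 ± 0.17, SRC1 intron 2 by 1.00 ± 0.18 and MRK1, a protein kinase gene, by 0.91 ± 0.17. RPL20B fell by 0.61 ± 0.18. Among 11 introns of mRNA processing and export genes 3 rose (3 adjusted over the list alone), among them SRC1 intron 1 (0.89 ± 0.18) and DBP2, an RNA helicase gene (0.69 ± 0.17; camera adjusted p = 0.027, and adjusted p = 0.938 with an estimated correlation). Ribosomal protein introns had a median of −0.13 against 0.14 (adjusted p = 5.34e-11, and adjusted p = 0.938 with an estimated correlation), with RPL20B as the call among 99 and 0 when adjusted over the list alone. Exon probes of these genes, subtracted in the index, had a median of 0.244, against 0.159 over all exon values. Limma called 0 junctions, also at an unadjusted p under 0.05, and 1 exon probe, SAR1 (−0.42 ± 0.10, against a median of 0.16), whereas 12 fell with exon centring (shift −0.16). Weighting arrays by spread gave 38 raised introns and 109 exon calls, and against hsp104 2 were higher. The direct comparison of mud1 and nam8 found SNC1 (1.52 against −0.07), UBC13 (1.21 against −0.04), IAI11 (1.16 against −0.15) and UBC8 (1.12 against 0.25) higher in mud1 and SAR1 lower (0.63 against 1.69). These 5 were 1 without the dye term, 0 to 2 with an array left out and 69 with arrays weighted by spread. Of the introns raised, 8 were shared, where independent lists would share 2.51.

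In mud2, which lacks a factor that binds at the branch point region, 93 introns rose and 3 fell, with a median of 0.41. EFM5 intron 2 rose by 2.25 ± 0.17, RIM1 by 2.17 ± 0.19, RUB1 by 2.02 ± 0.17 and SAR1 by 1.66 ± 0.19, and RPL20B fell by 0.82 ± 0.18. Ribosomal protein introns rose at 30 of 99 and fell at 3 (29 and 2 adjusted over the list alone; camera adjusted p = 0.00397, and adjusted p = 0.938 with an estimated correlation). At junctions RPS22B intron 1 (−0.82 ± 0.14) and YML6 fell and TDA5 rose (0.45 ± 0.10). Exon probes split 1 to 31, with RPS22B at −1.40 ± 0.14 and COX4 at −0.92 ± 0.12, and 7 to 17 with exon centring. Compared directly with mud1, 17 introns were higher in mud2, including RIM1 (2.17 against 0.63) and RPS19A (0.92 against −0.48), and TUB3 (−0.30 against 0.72) and PMI40 (0.03 against 1.16) were lower. The 19 introns were 8 without the dye term, 0 to 10 with an array left out and 105 with arrays weighted by spread. At exon probes COX5B, RPS22B and VPS75 differed, besides MUD1, the gene that mud1 lacks and the only junction to differ. The raised introns of the pair shared 43, with 23 expected of independent lists. Against hsp104 50 introns were higher in mud2, with an array left out 51 to 56 rose, and with weighted arrays 153.

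Deletion of either subunit of the nuclear cap-binding complex raised many introns. In gcr3, 142 of 214 introns rose and 4 fell by the index (median 0.75). Of 215 intron probes themselves 124 were higher and 15 lower as deposited (median 0.48). STO1, the deleted gene, had the highest index (6.65 ± 0.23), since its exon probe was lost. SAR1 rose by 2.89 ± 0.19, RPL16A by 2.77 ± 0.21 and PFY1, the profilin gene, by 2.67 ± 0.19. YRA1, an mRNA export gene, fell by 1.14 ± 0.28 and RPL20B by 1.10 ± 0.18. Ribosomal protein introns rose at 69 of 99 and fell at 2, secretion introns rose at 9 of 11 and ubiquitin and proteasome introns at 5 of 7 (the same when adjusted over the list alone). Junctions fell at 28 introns (8 to 11 with an array left out, 9 against hsp104 and 95 with arrays weighted by spread), led by RPL7B intron 1 (−1.76 ± 0.11) and RPS22B intron 1 (−1.23 ± 0.14). Of the 28, 22 were among the 96 ribosomal protein junctions (23 adjusted over the list alone; camera adjusted p = 0.000141, and adjusted p = 0.998 with an estimated correlation). At exon probes UBC4 (0.77 ± 0.15) and YRA1 (0.76 ± 0.17) rose and RPS22B stood at −1.70 ± 0.14, against a median of −0.31. Ribosomal protein exon probes fell at 61 of 97 (62), with a median of −0.42 that was −0.12 with exon centring (adjusted p = 0.00139, and adjusted p = 0.775 with an estimated correlation). The split of 15 to 113 was 60 to 52 with exon centring (shift 0.31) and 30 to 73 with centring on all probes (shift 0.16).

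In mud13, which lacks the small subunit, 108 of 215 introns rose and 1 fell by the index (median 0.46). Of 217 intron probes themselves 76 were higher and 13 lower as deposited (median 0.23). RPS26B rose by 1.84 ± 0.21, RPS19A by 1.74 ± 0.23, SAR1 by 1.72 ± 0.19 and RPS27B by 1.70 ± 0.23, and RPL20B fell by 0.59 ± 0.18. Of 99 ribosomal protein introns 61 rose (64 adjusted over the list alone), with a median of 0.66 against 0.24 (camera adjusted p = 0.0112, and adjusted p = 0.938 with an estimated correlation). At junctions RPS22B intron 1 (−1.25 ± 0.14) and both introns of RPL7B fell, among 4 called. The snoRNA host genes fell at 3 of their 11 junctions (4 adjusted over the list alone; adjusted p = 0.00197, and adjusted p = 0.998 with an estimated correlation). Exon probes split 8 to 100, with QCR10 (0.71 ± 0.14) and COX5B (0.60 ± 0.14) up and RPS22B (−1.12 ± 0.14) and CIN2 (−1.08 ± 0.11) down, and 33 to 34 with exon centring (shift 0.27) or 14 to 52 with centring on all probes (shift 0.12). Mitochondrial exon probes rose at 4 of 6 and fell at 1 (5 and 1 adjusted over the list alone; adjusted p = 4.83e-05, and adjusted p = 0.142 with an estimated correlation). The mud13 arrays lay further apart than most, with 2.81 times the median residual spread at exon probes. With arrays weighted by spread 50 introns and 4 exon probes were called, and on its own 2 arrays alone 0 exon probes.

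Compared directly, 25 introns were higher in gcr3 than in mud13 and 0 lower (1 at an unadjusted p under 0.05, limma). The arrays of mud13 lay far apart, and the introns that differed numbered 2 with arrays weighted by spread, 4 without the dye term and 10 to 26 with an array left out. The 25 included STO1, RPS14B (1.69 against −0.32), PFY1 (2.67 against 1.23) and UBC13 (2.55 against 1.34). At junctions 5 were lower in gcr3, among them RPS14B (−0.80 against 0.20). At exon probes 9 were lower, including RPS14B (−1.53 against 0.55), and 5 higher, including YRA1 (0.76 against −0.20) and RIM1 (0.28 against −0.67). The pair shared 104 raised introns, where independent lists would share 71.2, and 83 lowered exon probes, where they would share 50.2. Their intron indices correlated at r = 0.75 across introns, which are not independent replicates.

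Prp17 and Prp18 act at the second catalytic step, and their deletions lowered junctions as well as raising introns. In prp18, 33 introns had both a raised intron index and a lowered junction index, where independent calls would give 33.1. In prp17 there were 13, against 10.5 expected. The lowered junctions were thus not clearly those of the raised introns. In prp18, 155 of 207 introns rose and 3 fell (median 0.83). COF1 led (3.45 ± 0.17, or 10.9-fold), followed by EFB1, a translation elongation factor gene (2.35 ± 0.23), PMI40, a mannose metabolism gene (2.28 ± 0.18), and APE2, an aminopeptidase gene (2.07 ± 0.16), whereas RPL7B intron 1 fell by 0.98 ± 0.18. At junctions 50 fell (29 to 31 with an array left out and 101 with arrays weighted by spread) and 2 rose. SRB2 fell by 2.42 ± 0.24, POP8, a ribonuclease P subunit gene, by 2.04 ± 0.10, RPS22B intron 1 by 1.42 ± 0.14 and DCN1, a neddylation gene, by 1.29 ± 0.10. Ribosomal protein introns rose at 77 of 97 and fell at 2, and cytoskeleton introns rose at 9 of 11 (the same adjusted over the list alone). Junctions of snoRNA host genes fell at 10 of 11 (10 adjusted over the list alone; camera adjusted p = 0.00683, and adjusted p = 0.998 with an estimated correlation). At exon probes MRK1 (1.92 ± 0.13), QCR10 (1.64 ± 0.14) and QCR9 (1.20 ± 0.11), a pair of cytochrome bc1 subunits, rose and RPS14B fell (−1.68 ± 0.13). Ribosomal protein exon probes fell at 79 of 95 (79 adjusted over the list alone), with a median of −0.53 that was −0.32 with exon centring (adjusted p = 3e-20, and adjusted p = 0.166 with an estimated correlation). Mitochondrial exon probes rose at 4 of 6 (4; adjusted p = 0.00379, and adjusted p = 0.299 with an estimated correlation) and ubiquitin and proteasome ones at 5 of 8 (5; adjusted p = 0.0202, and adjusted p = 0.525 with an estimated correlation). The split was 43 to 100 as deposited and 73 to 72 with exon centring (shift 0.21).

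In prp17, 64 of 207 introns rose and 12 fell by the index (median 0.26). Of 209 intron probes themselves 56 were higher and 36 lower as deposited, with a median of 0.007. Exon probes of genes with introns had a median of −0.27. As deposited, the median shift of the index thus lay at the exon probes. Scaling of an array would move both kinds of probe alike. PMI40 (2.04 ± 0.18), COF1 (1.84 ± 0.17), APE2 (1.63 ± 0.16) and OM14, a mitochondrial outer membrane gene (1.58 ± 0.19), rose most, and HNT1 (−0.93 ± 0.17) and RPL20B (−0.92 ± 0.18) fell most. Ribosomal protein introns rose at 16 of 99 and fell at 9 (16 and 6 adjusted over the list alone), with a median of 0.15 against 0.39 (camera adjusted p = 0.000195, and adjusted p = 0.938 with an estimated correlation). At junctions 40 fell and 4 rose, with POP8 (−1.80 ± 0.10), SRB2 (−1.44 ± 0.24) and DCN1 (−1.43 ± 0.10) lowest. At exon probes UBC13 rose by 0.75 ± 0.12, and RPS14B (−1.56 ± 0.13) and RPL22B (−1.13 ± 0.10) were lowest. Ribosomal protein exon probes fell at 53 of 97 (56 adjusted over the list alone), with a median of −0.33 that was −0.08 with exon centring (adjusted p = 0.000122, and adjusted p = 0.723 with an estimated correlation). The split was 12 to 93, 48 to 36 with exon centring (shift 0.26) and 33 to 27 with centring on all probes (shift 0.22). Against hsp104 30 introns were higher in prp17 and 20 junctions lower, with an array left out 33 to 36 and 11 to 17, and with arrays weighted by spread 99 and 107.

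Compared directly, 71 of 198 introns were lower in prp17 than in prp18 and 1, TFC3, was higher. These 72 were 36 without the dye term, 15 to 43 with an array left out and 133 with arrays weighted by spread. COF1 stood at 1.84 against 3.45 (difference −1.61 ± 0.25) and RPS14A at −0.29 against 1.62. Limma found 0 junctions that differed (30 at an unadjusted p under 0.05, and also 30 with arrays weighted by spread). At exon probes 36 were lower in prp17, led by QCR10 (−0.44 against 1.64), MRK1 (0.03 against 1.92) and COX4 (−0.99 against 0.79), and 7 were higher, including GAL10 (0.19 against −0.60). With an array left out the 43 exon probes were 8 to 34. The pair shared 58 raised introns (44.8 expected of independent lists), 25 lowered junctions (9.33) and 65 lowered exon probes (40.8), and the junction indices correlated at r = 0.723 across introns. In a direct comparison of prp18 with prp4-1a, 190 of 203 introns were lower in prp18, for example RPL29 (0.88 against 5.20), and 1, SPO1, was higher. Junctions differed at 106 introns, 69 of them higher in prp18 such as RUB1 (0.00 against −3.14), and exon probes at 181. The pair shared 153 raised introns (150 expected) and 35 lowered junctions (26.6), and differed in temperature and background too.

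**Figure D2:**
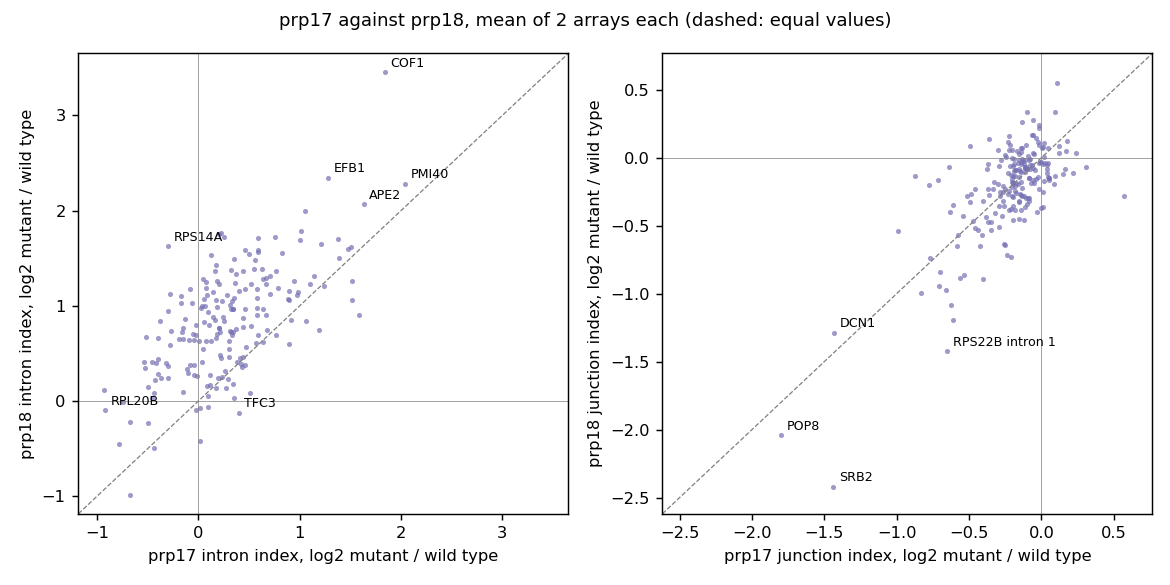
Intron index (left) and junction index (right) of prp17 (x axis) against prp18 (y axis), log2 mutant over wild type, each point an intron and the mean of 2 arrays per mutant, with a dashed line at equal values. Most introns lie above the line on the left, COF1 at 1.84 and 3.45, while junctions lie along it on the right, POP8 at −1.80 and −2.04.

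In dbr1, which lacks the enzyme that opens intron lariats, introns rose far and few junctions were called. Of 183 introns, 150 rose and 0 fell (limma; 0 also at an unadjusted p under 0.05), with a median index of 1.68. LSM7, an Lsm protein gene, rose by 7.10 ± 0.15 (137-fold), OM14 by 6.51 ± 0.19, RPS30B by 5.56 ± 0.17 and RPS11B by 5.49 ± 0.23. Limma called 1 junction, MPT5 (−0.65 ± 0.11), and with arrays weighted by spread 10 fell. At exon probes 6 rose, led by DBP2 (1.14 ± 0.09), and 4 fell, with PCH2, a meiotic checkpoint gene, lowest (−0.67 ± 0.15). The exon split was 10 to 12 with exon centring and 1 to 19 with centring on all probes (shift −0.21). Ribosomal protein introns rose at 86 of 89, with a median of 2.26 against 0.85 (camera adjusted p = 1.66e-05, and adjusted p = 0.938 with an estimated correlation). Ubiquitin and proteasome introns rose at 8 of 8, secretion introns at 8 of 9, cytoskeleton introns at 7 of 11, led by GIM5 (4.32 ± 0.15), and mRNA processing and export introns at 3 of 7. All these counts were the same adjusted over the list alone. REC107, a meiotic gene whose splicing depends on Mer1, had a raised intron (2.10 ± 0.14). Meiotic exon probes were lower than the rest (median −0.27 against 0.11), with PCH2 and HOP2 (−0.44 ± 0.13) called of 7 (2 adjusted over the list alone), at adjusted p = 0.00212 (camera), adjusted p = 0.0493 with an estimated correlation and adjusted p = 0.105 with ribosomal protein genes left out of the comparison set. Whether the sporulating cells that the labels describe or the deletion lies behind this cannot be separated here. Against hsp104 135 introns were higher and 0 junctions differed.

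**Figure D3:**
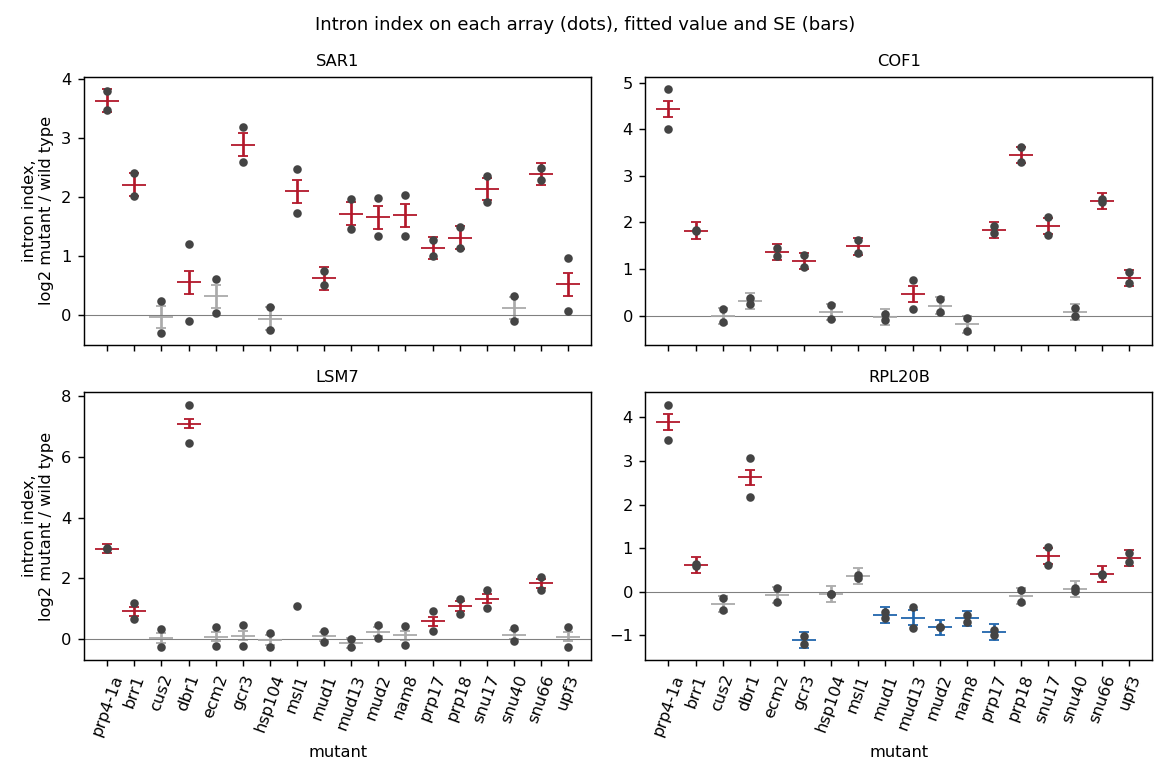
Intron index (log2 mutant over wild type) of SAR1, COF1, LSM7 and RPL20B in each of 18 mutants, with dots for single arrays and bars for the fitted value and its standard error, red where raised, blue where lowered and grey where not called. SAR1 is called in 14 of 18 mutants, LSM7 reaches 7.10 in dbr1, and RPL20B is lowered in 6 mutants.

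In upf3, which lacks a factor of nonsense-mediated decay, 76 of 207 introns rose and 1 fell (median 0.35). RPL35B rose by 1.25 ± 0.19, PRE3, a proteasome subunit gene, by 1.22 ± 0.22, RPS14A by 1.17 ± 0.15 and RPS13 by 1.13 ± 0.27, and MAF1, a gene of the repressor of RNA polymerase III, fell by 0.63 ± 0.17. RPL28, whose unspliced RNA is a known substrate of this decay, rose by 0.88 ± 0.24 and RPL30 by 1.05 ± 0.20. Of 98 ribosomal protein introns 53 rose (57 adjusted over the list alone), with a median of 0.57 against 0.16 (camera adjusted p = 7.05e-07, and adjusted p = 0.938 with an estimated correlation), and none of 11 mRNA processing and export introns passed either way (median 0.00; adjusted p = 0.00325, and adjusted p = 0.938 with an estimated correlation). At junctions RPL22B (−1.30 ± 0.09) and MRK1 (−0.58 ± 0.11) fell and REC114, a meiotic recombination gene, rose (1.12 ± 0.10), among 4 lowered and 2 raised. At exon probes REC107 (1.60 ± 0.13), IWR1 (1.27 ± 0.13), the meiotic helicase gene HFM1 (1.14 ± 0.14) and RPL22B (0.98 ± 0.10) rose most, and COX4 (−0.82 ± 0.12) and PMI40 (−0.77 ± 0.17) were lowest. Meiotic exon probes rose at 3 of 7 and fell at 1 (the same adjusted over the list alone; adjusted p = 0.000994, adjusted p = 0.0493 with an estimated correlation and adjusted p = 0.0612 with ribosomal protein genes left out of the comparison set). REC107 and HFM1 were the 2 members on the array of the list of Mer1-dependent introns, too few for a test. The split was 15 to 48, 37 to 10 with exon centring (shift 0.16) and 23 to 18 with centring on all probes (shift 0.11). Against hsp104 31 introns were higher, on its own 2 arrays alone 45 rose, and with an array left out 14 to 37 did, where exon calls were 13 to 16.

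In ecm2, which lacks a protein of the activated spliceosome, 8 of 201 introns rose and 0 fell (limma; 3 fell at an unadjusted p under 0.05). TAN1 rose by 1.51 ± 0.14, COF1 by 1.37 ± 0.17 and APE2 and MAF1 by 0.64 each (± 0.16 and ± 0.17). Junctions fell at 6 introns, led by RPL7B intron 1 (−0.55 ± 0.11). At exon probes RPL29 (0.78 ± 0.18) rose most and GCR1, an activator of glycolytic genes, fell (−0.74 ± 0.12). Ribosomal protein exon probes rose at 45 of 97 (56 adjusted over the list alone), with a median of 0.33 that was 0.16 with exon centring (camera adjusted p = 1.02e-17, and adjusted p = 0.229 with an estimated correlation). The exon split was 55 to 5, 23 to 26 with exon centring (shift −0.17) and 11 to 23 with centring on all probes (shift −0.13). Against hsp104 2 introns were higher and 0 junctions differed, and on its own 2 arrays alone 3 introns rose. The 60 exon calls were 0 to 1 with an array left out and 0 on its own 2 arrays alone.

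In snu40 and hsp104, the latter a chaperone deletion outside mRNA processing that was taken as the control strain, almost no gene passed at the shared spread. For snu40, limma called 0 of 186 introns and 0 junctions, against 7 and 1 at an unadjusted p under 0.05. At exon probes KEI1, a sphingolipid synthesis gene, fell (−0.61 ± 0.10), against 19 at an unadjusted p. With arrays weighted by spread 29 introns rose in snu40 and 67 exon probes were called. For hsp104, limma called 0 of 204 introns, 0 junctions and 0 exon probes, and 0 of each also at an unadjusted p under 0.05, where 10.2 introns would be expected by chance. The hsp104 arrays had 0.555 times the median spread at introns, so the shared spread made this test strict. The counts of hsp104 also stayed at 0 with arrays weighted by spread and on its own 2 arrays alone. RPS14B (0.28 ± 0.14) and COX5B (0.31 ± 0.18) are examples of its intron indices. In self-tests on simulated data in the prp18 setting, 44.4% of introns changed by 0.5 were recovered.

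Over the 17 deletions and prp4-1a, 201 of 222 introns rose in at least 5 mutants, 80 in at least 10 and 2 in none. By the index, GCR1 and SAR1 rose in 14 of 18, APE2 in 13 of 17, and ERV41, IWR1, RPL16A and RUB1 in 13 of 18. RPL20B was the intron most often lowered (6 of 18). Junctions of RPS22B intron 1 and YML6 fell in 9 mutants. CIN2 exon probes fell in 12 mutants, GCR1 exon probes in 11 and those of SAR1 and RPL16A in 10 each. A fall of the exon probe raises the index, so a raised index of these genes need not mean more intron RNA. For GCR1 the index was 0.59 in ecm2 with the exon probe at −0.74, and 0.47 in prp17 with −0.54. The intron indices most alike were those of brr1 and msl1 (r = 0.779 across introns), brr1 and snu66 (r = 0.76), gcr3 and mud13 (r = 0.75) and msl1 and snu17 (r = 0.75). Whether arrays shared wild-type RNA is not given in the sources used here, so part of these correlations and of the shared calls may come from it. Pairs of strains without a called intron correlated at r = 0.244 (cus2 and hsp104), 0.183 (cus2 and snu40) and 0.082 (hsp104 and snu40). After the mean of the other deletion strains was removed these pairs reached 0.86, 0.803 and 0.843, above the 0.594 of prp17 and prp18, so that step does not separate shared effects from none.

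Ribosomal protein introns were compared with the others in each mutant by a permutation test across introns (in both directions, adjusted over mutants and measures; 3.27e-05 is the smallest adjusted p it gave). The permutation takes introns as independent, and camera passed none of these differences with an estimated correlation (0.651; adjusted p of 0.938 or more in each mutant). Ribosomal protein introns stood higher in prp4-1a (mean difference 1.40), dbr1 (1.14), upf3 (0.38) and mud13 (0.35), each at adjusted p = 3.27e-05, although the mud13 value ranged from 0.0882 to 0.63 with an array left out. They stood lower in mud1 (−0.51), prp17 (−0.34), nam8 (−0.33) and ecm2 (−0.24) at the same p, in snu66 (−0.25, adjusted p = 0.0037) and in mud2 (−0.24, adjusted p = 0.000672, and −0.17 at adjusted p = 0.0503 over probes present on all arrays). In these strains, dbr1 and prp17 excepted, ribosomal protein exon medians differed from the all-exon median in the direction opposite to the index. Examples are prp4-1a (−2.32 against −1.24), mud1 (0.217 against 0.0116) and ecm2 (0.33 against 0.164). In dbr1 (0.183 against 0.103) and prp17 (−0.334 against −0.258) the direction was the same. The share of each difference due to exon probes was not tested. Strains with no called intron gave small differences of the same sign, −0.15 in cus2 and −0.11 in snu40 at adjusted p = 3.27e-05 and −0.06 in hsp104 at adjusted p = 9e-05, and whether these come from the measure or from small changes was not tested. In msl1 (−0.14, adjusted p = 0.05), prp18 (0.14, 0.0952), brr1 (−0.09, 0.272), snu17 (0.03, 0.724) and gcr3 (−0.00, 0.978) no difference passed. The msl1 difference did pass with spots joined by their median and with at least 2 usable spots. Over all mutants camera passed 24 of 129 intron tests with a preset correlation and 0 with an estimated correlation, 12 of 129 and 0 at junctions, and 38 of 144 and 3 at exon probes. With ribosomal protein genes left out of the comparison sets, 0 tests of the other lists passed for introns, 2 for junctions and 7 for exon probes. Many ribosomal protein genes have near-identical copies, and their probes may bind RNA of both.

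**Figure D4:**
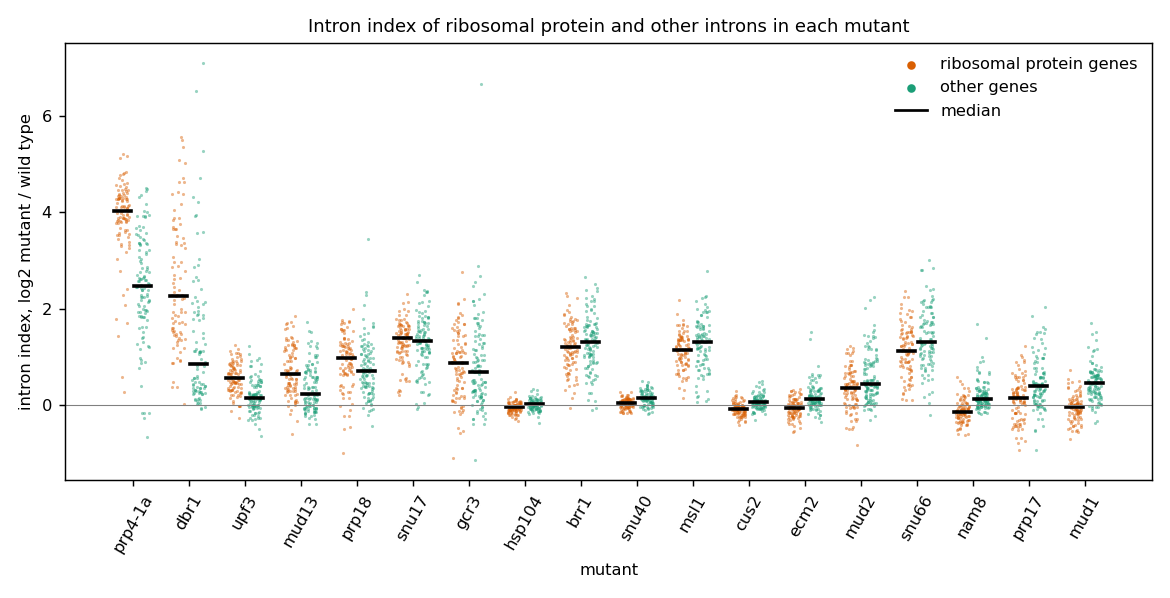
Intron index (log2 mutant over wild type, mean of 2 arrays) of ribosomal protein introns (orange) and other introns (green) in each of 18 mutants, each point an intron and black bars the medians, ordered by the difference of means. The difference runs from 1.40 in prp4-1a to −0.51 in mud1, and hsp104, the control strain, stands at −0.06.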

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

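The tests of the dbr1 junctions and intron probes and of the STO1 intron probe were chosen only after the result was seen.

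Several pairs of mutants differed in a direct test, which is why their counts appear here. Between prp17 and prp18, 72 introns and 43 exon probes differed. Between gcr3 and mud13 the numbers were 25 introns, 5 junctions and 14 exon probes. Between mud1 and nam8 they were 5, 1 and 1, and between mud1 and mud2 19, 1 and 4. Between msl1 and cus2 158 introns, 6 junctions and 43 exon probes differed. Between snu66 and prp4-1a the numbers were 177, 101 and 177, and between prp18 and prp4-1a 191, 106 and 181.

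Probes outside the indices gave signals above those of hsp104, the control strain. Among 66 probes without a gene symbol 34 were higher than hsp104 in at least 1 mutant, and among 20 tested probes of uncertain role 14 were. Taking the highest probe for each symbol and for none, these were probe 26, without a symbol, in dbr1 (5.26), an ACT1 probe (position 815) in dbr1 (4.76), an HMRA1 probe (position 110) in prp4-1a (3.34) and an MTR2 probe (position 478) in dbr1 (2.94).

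The 2 arrays of mud13 lay further apart than those of other deletion strains, with 2.81 times the median spread at exon probes. An array of an unrelated sample under the mud13 label is argued against, since the array less like gcr3 still correlated with it at r = 0.576 (0.757 for the other). A difference confined to ribosomal protein genes is argued against too, since the spread without them was 2.72 times the median. No biological explanation was tested, and separate cultures or hybridisations remain open.

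In dbr1, 150 introns rose while 1 junction was called, as lariats that outlast splicing would give. Less splicing would also raise introns, and it stays open: the median junction index over those introns was −0.051 and 0.0199 on the dbr1 arrays, within the −0.17 to 0.0112 of 12 arrays of 6 strains with many raised introns on the first array and just above it on the second. A fall of the exon probes as the source of the raised index is argued against, since 96.7% of these introns (145 of 150) were higher at the intron probe itself.

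The STO1 intron probe was higher in gcr3 although the gene is deleted. Whether it reads an RNA which does not follow splicing stays open. Its index rose in 8 of 16 other mutants, which only just meets the bound set for this test. That count cannot decide the question, since the index also rises where the exon probe falls, as the STO1 exon probe did in brr1. In snu17 the STO1 index rose without a fall of the exon probe. That part of the intron remained in the deleted locus stays open: the intron probe averaged 1.06 on the gcr3 arrays and the exon probe −5.59. The extent of the deletion is not given in the sources used here.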

How the results depend on the processing

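The alternatives with zeros kept, with at least 2 usable spots and with array weights were chosen only after the result was seen. Raised introns in prp4-1a, brr1, dbr1, gcr3, msl1, prp18, snu17 and snu66 stayed within 1.5 times their number with each alternative except the fit to probes present on all 36 arrays, which tests fewer introns. Of 2167 values of named genes under alternatives other than a left-out array, 2022 kept direction and side of the threshold, 143 kept direction only and 2 reversed; of 386 with an array left out, 312, 73 and 1 did. Except where fewer items or arrays were used, the cause was not tested. The split by intron length, its Spearman correlation and the splice site classes were not run, since no genome was used here. Probe signal over background is unknown, which limits what a count of 0 excludes. With an array left out, the remaining array is assumed to vary like those of other mutants. Named genes that kept direction only are counted above and not listed singly. Other results without a value here stayed on their side of the threshold, within 1.5 times for counts, or within 1 SD for values with no test.

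After centring on all probes, the exon calls numbered 20 in dbr1, 34 in ecm2, 37 in msl1, 31 in mud1, 66 in mud13, 7 in nam8, 60 in prp17, 3 in snu40, 60 in snu66 and 41 in upf3. The calls over all probes were 2 in snu40. The exon differences were 15 for msl1 against cus2. The log ratios were 0.0319 for prp4-1a exon of HFM1 and 1.22 for gcr3 STO1 intron probe.

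After exon centring, the exon calls numbered 22 in dbr1, 35 in msl1, 74 in mud1, 67 in mud13, 12 in nam8, 43 in snu17, 3 in snu40 and 54 in snu66. Exon differences came to 10 for mud1 against mud2 and 15 for msl1 against cus2. Log ratios came to 0.73 for prp4-1a exon of HFM1 and 1.36 for gcr3 STO1 intron probe.

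Without the dye term, the block that pairs the arrays (no replicate block), the raised introns numbered 2 in ecm2 and 26 in mud1. Here lowered junctions numbered 15 in brr1, 2 in ecm2, 18 in gcr3, 8 in msl1, 1 in mud1, 1 in mud2 and 2 in upf3. Here exon calls numbered 1 in dbr1, 26 in ecm2, 11 in mud1, 14 in mud2, 0 in nam8, 48 in snu17, 0 in snu40, 13 in snu66 and 31 in upf3. Here calls over all probes numbered 37 in ecm2, 42 in mud1, 91 in mud2, 9 in nam8, 0 in snu40 and 124 in upf3. Here intron differences numbered 36 for prp17 against prp18, 4 for gcr3 against mud13, 1 for mud1 against nam8 and 8 for mud1 against mud2. Here junction differences numbered 2 for msl1 against cus2. Here exon differences numbered 14 for prp17 against prp18, 5 for gcr3 against mud13, 2 for mud1 against mud2 and 16 for msl1 against cus2.

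Over probes present on all 36 arrays, the raised introns numbered 136 in prp4-1a, 131 in brr1, 88 in gcr3, 21 in mud1, 50 in mud2 and 39 in prp17. The lowered junctions were 21 in mud1. The intron differences were 11 for gcr3 against mud13 and 10 for mud1 against mud2. The difference of ribosomal protein minus other introns was 0.11 in gcr3 (permutation adjusted p = 0.42) and −0.17 in mud2 (permutation adjusted p = 0.0503). The difference of ribosomal protein minus other junctions was −0.0500 in brr1 (permutation adjusted p = 0.105). The correlation r of intron indices was 0.678 for prp17 and prp18, 0.876 for gcr3 and mud13 and 0.516 for mud1 and mud2. The correlation r of junction indices was −0.064 for msl1 and cus2 and 0.261 for prp18 and prp4-1a.

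With trend and robust spread, the exon calls numbered 17 in dbr1.

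In a fit of deletion strains without prp4-1a and dbr1, the raised introns numbered 13 in ecm2 and 20 in nam8. Here lowered junctions numbered 44 in brr1, 59 in ecm2, 51 in gcr3, 62 in mud1, 7 in mud13, 7 in mud2, 73 in prp17, 76 in prp18, 23 in snu17, 32 in snu66 and 17 in upf3. Here exon calls numbered 70 in mud1 and 9 in nam8. Here calls over all probes numbered 201 in ecm2, 223 in mud1, 219 in mud2, 53 in nam8, 2 in snu40 and 332 in upf3. Here intron differences numbered 121 for prp17 against prp18, 51 for gcr3 against mud13, 28 for mud1 against nam8 and 58 for mud1 against mud2. Here junction differences numbered 9 for prp17 against prp18, 12 for gcr3 against mud13 and 15 for msl1 against cus2. Here exon differences numbered 7 for mud1 against mud2 and 68 for msl1 against cus2.

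At a threshold of 0.01, the raised introns numbered 3 in ecm2, 33 in mud1, 42 in prp17 and 39 in upf3. The lowered junctions were 11 in brr1, 3 in ecm2, 13 in gcr3, 9 in msl1, 1 in mud1, 1 in mud2, 24 in prp17, 7 in snu17, 7 in snu66 and 2 in upf3. The exon calls were 3 in dbr1, 18 in ecm2, 52 in msl1, 8 in mud1, 65 in mud13, 19 in mud2, 0 in nam8, 58 in prp17, 54 in snu17, 16 in snu66 and 28 in upf3. The calls over all probes were 29 in ecm2, 36 in mud1, 171 in mud13, 11 in nam8, 205 in prp17 and 119 in upf3. The intron differences were 30 for prp17 against prp18, 13 for gcr3 against mud13, 1 for mud1 against nam8 and 8 for mud1 against mud2. The junction differences were 2 for gcr3 against mud13, 0 for mud1 against nam8, 0 for mud1 against mud2 and 2 for msl1 against cus2. The exon differences were 20 for prp17 against prp18, 7 for gcr3 against mud13, 2 for mud1 against mud2 and 20 for msl1 against cus2.

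With spots joined by their median, the lowered junctions numbered 2 in dbr1 and 11 in msl1. Exon calls came to 0 in nam8. Junction differences came to 1 for prp17 against prp18, 0 for mud1 against nam8 and 0 for mud1 against mud2. For the difference of ribosomal protein minus other introns, the value was −0.15 in msl1 (permutation adjusted p = 0.0455). For the correlation r of intron indices, the value was 0.634 for prp17 and prp18 and 0.529 for mud1 and mud2. For the correlation r of junction indices, the value was 0.276 for prp18 and prp4-1a. Log ratios came to −1.75 for mud1 MUD1 intron probe and −2.72 for mud1 MUD1 exon probe.

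With zeros kept, the raised introns numbered 4 in ecm2. Here lowered junctions numbered 12 in brr1, 12 in msl1, 2 in mud1, 1 in mud2 and 1 in upf3. Here exon calls numbered 6 in dbr1 and 2 in nam8. Here junction differences numbered 1 for prp17 against prp18 and 2 for msl1 against cus2. With this choice the difference of ribosomal protein minus other introns was 0.0310 in gcr3 (permutation adjusted p = 0.786). Under it, the correlation r of intron indices was 0.504 for mud1 and mud2. Under it, the correlation r of junction indices was 0.689 for prp17 and prp18 and 0.229 for prp18 and prp4-1a. Here log ratios numbered −1.36 for mud1 MUD1 intron probe.

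With at least 2 usable spots, the lowered junctions numbered 0 in dbr1, 10 in ecm2 and 20 in mud1. The difference of ribosomal protein minus other introns was −0.19 in msl1 (permutation adjusted p = 0.0146). The difference of ribosomal protein minus other junctions was −0.0572 in brr1 (permutation adjusted p = 0.0803). The correlation r of intron indices was 0.662 for prp17 and prp18, 0.842 for gcr3 and mud13, 0.57 for mud1 and mud2 and 0.278 for prp18 and prp4-1a. The correlation r of junction indices was −0.0106 for msl1 and cus2 and 0.244 for prp18 and prp4-1a.

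With array weights, the raised introns numbered 2 in cus2, 23 in ecm2, 106 in mud1, 50 in mud13, 153 in mud2, 38 in nam8, 99 in prp17, 29 in snu40 and 120 in upf3. Lowered junctions came to 47 in prp4-1a, 62 in brr1, 10 in dbr1, 43 in ecm2, 95 in gcr3, 44 in msl1, 126 in mud1, 2 in mud13, 21 in mud2, 107 in prp17, 101 in prp18, 39 in snu66 and 89 in upf3. Exon calls came to 60 in dbr1, 100 in ecm2, 164 in msl1, 117 in mud1, 4 in mud13, 81 in mud2, 109 in nam8, 67 in snu40, 67 in snu66 and 152 in upf3. Calls over all probes came to 227 in ecm2, 403 in mud1, 39 in mud13, 319 in mud2, 211 in nam8, 153 in snu40 and 460 in upf3. Intron differences came to 133 for prp17 against prp18, 2 for gcr3 against mud13, 69 for mud1 against nam8 and 105 for mud1 against mud2. Junction differences came to 30 for prp17 against prp18, 1 for gcr3 against mud13, 45 for mud1 against nam8, 63 for mud1 against mud2, 17 for msl1 against cus2, 26 for snu66 against prp4-1a and 30 for prp18 against prp4-1a. Exon differences came to 2 for gcr3 against mud13, 38 for mud1 against nam8, 87 for mud1 against mud2 and 130 for msl1 against cus2.

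On the 2 arrays of the mutant alone, the raised introns numbered 3 in ecm2, 6 in nam8 and 45 in upf3. Here lowered junctions numbered 36 in prp4-1a, 37 in brr1, 4 in dbr1, 0 in ecm2, 48 in mud1, 0 in mud13, 0 in mud2, 22 in prp18, 1 in snu17 and 1 in upf3. Here exon calls numbered 2 in dbr1, 0 in ecm2, 46 in mud1, 0 in mud13, 0 in nam8, 89 in prp18, 42 in snu17, 77 in snu66 and 32 in upf3. Here calls over all probes numbered 39 in ecm2, 133 in mud1, 1 in mud13, 0 in nam8, 2 in snu40 and 43 in upf3.

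Against hsp104, the raised introns numbered 2 in ecm2, 19 in mud1, 71 in mud13, 50 in mud2, 2 in nam8, 30 in prp17 and 31 in upf3. The lowered junctions were 4 in brr1, 0 in dbr1, 0 in ecm2, 9 in gcr3, 5 in msl1, 1 in mud1, 2 in mud13, 1 in mud2, 20 in prp17, 2 in snu17, 4 in snu66 and 1 in upf3. The exon calls were 1 in dbr1, 1 in ecm2, 43 in msl1, 4 in mud1, 67 in mud13, 11 in mud2, 0 in nam8, 61 in prp17, 49 in snu17, 8 in snu66 and 33 in upf3. The calls over all probes were 11 in ecm2, 16 in mud1, 162 in mud13, 75 in mud2, 5 in nam8, 202 in prp17, 0 in snu40 and 101 in upf3.

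After the mean of the other deletion strains was removed, the correlation r of intron indices was 0.594 for prp17 and prp18, 0.312 for mud1 and mud2 and −0.351 for msl1 and cus2. For the correlation r of junction indices, the value was 0.675 for prp17 and prp18, 0.115 for mud1 and mud2, −0.244 for msl1 and cus2 and 0.214 for prp18 and prp4-1a.

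With an estimated correlation, the gene list tests passing numbered 0 for intron, 0 for junction and 3 for exon.

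With ribosomal protein genes left out of the comparison sets, the gene list tests passing numbered 0 for intron, 2 for junction and 7 for exon.

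With each array left out in turn, the raised introns ranged over 2 in ecm2, 12 to 15 in mud1, 67 to 98 in mud13, 51 to 56 in mud2, 3 to 4 in nam8, 33 to 36 in prp17 and 14 to 37 in upf3. The lowered junctions ranged over 4 to 5 in brr1, 0 to 1 in dbr1, 0 in ecm2, 8 to 11 in gcr3, 1 to 7 in msl1, 1 to 2 in mud1, 2 to 29 in mud13, 0 to 1 in mud2, 11 to 17 in prp17, 29 to 31 in prp18, 3 to 7 in snu17, 2 to 4 in snu66 and 1 to 3 in upf3. The exon calls ranged over 45 to 70 in brr1, 1 to 4 in dbr1, 0 to 1 in ecm2, 76 to 105 in gcr3, 22 to 31 in msl1, 1 to 10 in mud1, 69 to 113 in mud13, 8 to 15 in mud2, 0 in nam8, 33 to 57 in prp17, 89 to 114 in prp18, 36 to 46 in snu17, 0 in snu40, 10 to 11 in snu66 and 13 to 16 in upf3. The calls over all probes ranged over 267 to 337 in brr1, 11 to 15 in ecm2, 275 to 322 in gcr3, 242 to 317 in msl1, 11 to 24 in mud1, 62 to 66 in mud2, 2 to 8 in nam8, 135 to 172 in prp17, 0 in snu40 and 70 to 85 in upf3. The intron differences ranged over 15 to 43 for prp17 against prp18, 10 to 26 for gcr3 against mud13, 0 to 2 for mud1 against nam8 and 0 to 10 for mud1 against mud2. The junction differences ranged over 0 to 1 for prp17 against prp18, 0 to 33 for gcr3 against mud13, 0 for mud1 against nam8, 0 for mud1 against mud2 and 0 to 2 for msl1 against cus2. The exon differences ranged over 8 to 34 for prp17 against prp18, 5 to 30 for gcr3 against mud13, 2 to 3 for mud1 against mud2 and 15 to 33 for msl1 against cus2. The difference of ribosomal protein minus other introns ranged over −0.13 to 0.16 in gcr3, −0.16 to −0.0911 in msl1, 0.0882 to 0.63 in mud13, 0.0852 to 0.21 in prp18, −0.0367 to 0.13 in snu17 and −0.28 to −0.19 in snu66. The difference of ribosomal protein minus other junctions ranged over 0.0209 to 0.80 in prp4-1a, −0.0871 to −0.0318 in brr1, −0.0653 to −0.0132 in cus2, −0.0667 to 0.00770 in dbr1, −0.000856 to 0.0276 in hsp104, −0.11 to −0.0505 in msl1, −0.10 to −0.0457 in mud1, −0.18 to 0.0421 in mud13, −0.0401 to −0.00884 in nam8, −0.0625 to 0.0470 in snu17, −0.0500 to −0.00398 in snu40, −0.0113 to 0.0659 in snu66 and −0.13 to −0.00344 in upf3. The exon probe of HFM1 in prp4-1a ranged over −0.83 to 0.14.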

Other observations

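All tests in this part were chosen only after the result was seen.

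Probes of genes whose probe order left the role uncertain mostly rose in prp18 (13 up and 1 down of 17 tested), gcr3 (12 and 2 of 19) and snu66 (10 and 0 of 17). In msl1 (9 and 1 of 19), dbr1 (6 and 0 of 17) and brr1 (6 and 1 of 17) most were not called, and more rose than fell. Calls went both ways in prp4-1a (11 and 6), snu17 (6 and 5) and mud13 (2 and 3). For HMRA1, which has more than 1 intron, the probe at position 110 stood at 3.34 in prp4-1a, 2.74 in snu17 and 2.20 in brr1. For ACT1, the probe at position 815 stood at 4.76 in dbr1 and 2.90 in prp4-1a, and that at position 813 at −1.87 in prp4-1a. For MTR2, positions 477 and 478 stood at 2.44 and 2.94 in dbr1.

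A first hypothesis was that deletions acting at the second step lower junctions more, relative to raised introns, than other deletions. The ratio of lowered junctions to raised introns was 0.625 in prp17 and 0.323 in prp18, and at most 0.197 in the other deletion strains compared. Among 11 deletion strains with many raised introns, dbr1 left out, this ranking gave p = 0.0182 (exact permutation, 55 splits, in the predicted direction). The ranking was not kept under every alternative, so the hypothesis stays open. With arrays weighted by spread the ratio was 1.19 in mud1 against 1.08 in prp17 and 0.574 in prp18 (exact permutation p = 0.127), over probes present on all 36 arrays it was 1 in mud1 against 0.949 and 0.44 (p = 0.0545, exact permutation), and on the 2 arrays of each mutant alone the exact permutation p was 0.164. In the fit of deletion strains (0.816 in mud1, 0.45 in prp18) and with at least 2 usable spots (0.426 and 0.336) mud1 lay above prp18 too, each at exact permutation p = 0.0364.

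Another hypothesis was that loss of Mud1, Nam8 or Mud2, factors of the U1 snRNP or the branch point region, spares ribosomal protein introns. Ribosomal protein minus other introns averaged −0.36 in mud1, nam8 and mud2 and −0.04 in the other deletion strains without dbr1, with p = 0.0107 (exact permutation, 560 splits of 16 strains, in the predicted direction). With dbr1 the others averaged 0.047 (exact permutation p = 0.00882, 680 splits). The others include strains that lack U2 or U2-associated factors, at −0.14 in msl1, −0.15 in cus2 and 0.03 in snu17. In mud2 30 of 99 ribosomal protein introns still rose, so they were not spared outright there. The index subtracts the exon probe, and ribosomal protein exon probes stood above the median of all exon values in these 3 strains. Their medians were 0.217 in mud1, 0.244 in nam8 and −0.0567 in mud2, against 0.0116, 0.159 and −0.0895. A lower index therefore need not mean less unspliced RNA from these introns. Strains with no raised intron also gave −0.15 (cus2), −0.11 (snu40) and −0.06 (hsp104), and prp17 (−0.34), snu66 (−0.25) and ecm2 (−0.24) lay as low as mud2 (−0.24) although their factors act elsewhere. The low values are therefore not confined to these 3 strains, and both hypotheses were found and tested on the same data. Which feature of ribosomal protein introns this may follow was not analysed here.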
